A study of Homo sapiens with 24 samples.

How the data were processed

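The analysed file is the GENCODE human gene annotation, version 21 (Ensembl 77), on GRCh38, per the file headers. It holds 2546594 feature lines, of which 0 have an entry in the score column and 0 name a sample title or accession. It therefore holds no count, signal, peak or comparison of the 24 libraries. GRCh38 and deepTools are named in the submitters' processing notes without a role. The aligner, any peak caller and the step that used the annotation are not given in the sources used here.

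Libraries were grouped by target and condition from their titles, which also give the replicate. Tests between conditions were planned for H3K4me1 and H3K27ac before the data were examined. With 0 libraries having a value analysed here, none of those tests was run, under any setting.

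Gene and transcript positions (1-based) were read from the deposited annotation with Python 3.11.15. The genes described are members of 8 lists, 59 genes in all, fixed before the data were examined, and neighbours of theirs are named as found in the annotation; the other part of the naming rule, the regions with the largest changes, yielded none because no change was measured. Those quoted with coordinates or distances are examples chosen after their values were seen. A transcript's start site was its first base on its strand, and identical positions of one gene were counted once. A gene's start sites were called spread if the first and last lay more than 1000 bp apart. A neighbour was any other gene, of any type and strand, with a start site at most 1000 bp from one of the gene's own. Both counts were chosen after seeing that the file is an annotation, as were their alternatives: a 2000 bp window, protein-coding neighbours alone and basic transcripts alone. No p-value was computed.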

Results

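Chromatin immunoprecipitation (ChIP) measurements of this series were not analysed here. The file analysed here is a human gene annotation, which carries gene positions and no value from any library. The conditions were therefore not compared, and the gene positions and gene counts given below describe the annotation, not the cells.

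The labels describe 24 ChIP-seq libraries from H9, an established human embryonic stem cell line. ChIP-seq recovers and sequences the DNA bound to a chosen protein or histone modification. The libraries fall into 12 groups of 2 biological replicates, made of 3 library types in 4 conditions. The library types are input DNA, H3K4me1 (a histone methylation found at enhancers and around promoters) and H3K27ac (a histone acetylation found at active enhancers and promoters). The conditions are undifferentiated cells, cells differentiated towards mesendoderm for 24 h, and the same differentiation with either hydroxyurea or nocodazole. Mesendoderm is the embryonic progenitor of mesoderm and endoderm. Hydroxyurea stalls DNA replication, and nocodazole disrupts microtubules and holds cells at mitosis. Per the treatment protocol in the labels, cells were first synchronised with nocodazole at 100 ng/ml for 16 h, and differentiation began once it was removed, so all 3 differentiated conditions had this earlier exposure. The protocol does not say whether the undifferentiated cells were synchronised too. Hydroxyurea was present from the start of differentiation, and in the nocodazole condition the drug was added again 8 h into it. The treatment label gives hydroxyurea and other compounds in mM. Those doses are not reported here, because the unit looked too high and was not checked. The other compounds are not named here. The series asked how cell division bears on differentiation, per its title. Differences in H3K4me1 or H3K27ac between these conditions were not analysed here, and the depth of the libraries was not analysed here.

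The annotation was GENCODE version 21 on GRCh38, with 60155 genes and 196327 transcripts. All 59 genes of the 8 lists fixed before the data were examined were found once, by symbol, and all are annotated as protein-coding. Among the mesendoderm genes, T (brachyury, a T-box transcription factor) lies on the minus strand of chromosome 6 from 166157656 to 166168700. EOMES, another T-box factor, lies on the minus strand of chromosome 3 from 27715949 to 27722711. MIXL1, a homeobox factor, lies on the plus strand of chromosome 1 from 226223618 to 226227054. Of the pluripotency genes, POU5F1 (OCT4) lies on the minus strand of chromosome 6 from 31164337 to 31180731, and NANOG on the plus strand of chromosome 12 from 7787794 to 7799141. SOX17, an endoderm transcription factor, lies on the plus strand of chromosome 8 from 54457935 to 54460888.

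The start sites of all annotated transcripts were counted, because a promoter window, where a ChIP-seq study uses one, is placed on such sites. Each site is the first base of a transcript model of any type. That it marks a promoter was not measured here. Whether this series used such windows is not given in the sources used here. Start sites spanned more than 1000 bp in 42 of the 59 listed genes (71.2%), and in 13571 of the 19881 protein-coding genes of the annotation (68.3%). POU5F1 had 6 start sites over 13893 bp, and GATA4 had 9 over 79534 bp. EOMES had 3 start sites within 399 bp, and SOX2, SOX17, GSC and CER1 had 1 each. By list, the span exceeded 1000 bp in 7 of 10 pluripotency genes, 8 of 13 mesendoderm genes, 4 of 6 definitive endoderm genes and 3 of 6 mesoderm genes. It did so in 3 of 5 neuroectoderm genes, 4 of 4 extra-embryonic genes, 8 of 10 cell cycle and checkpoint genes and 5 of 5 housekeeping genes. With the transcripts that GENCODE tags as basic alone, 19 of the 59 genes exceeded this span. That count was not made over all protein-coding genes. The spans given for POU5F1 and GATA4 are over all their transcripts. Whether these genes were among the 19 was not recorded.

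A start site of another gene lay within 1000 bp of a start site of 17 of the 59 listed genes (28.8%). The same held for 7705 of the 19881 protein-coding genes (38.8%). ZIC1 and ZIC4, which lie on opposite strands, had their closest start sites 8 bp apart, and ZIC1 had 5 start sites over 114519 bp. The closest start sites of WNT3 and WNT9B, both Wnt ligand genes on opposite strands, were 47 bp apart. WNT3 had 4 start sites over 14394 bp. Whether these pairs remain with basic transcripts alone was not recorded. LHX1 and an antisense gene had their closest start sites 124 bp apart, and GATA6 and GATA6-AS1 475 bp apart. The neighbours counted were of mixed types. That of MESP1 was a processed pseudogene, 986 bp away, and that of ACTB was a microRNA gene on the same strand, 88 bp away. None of the 6 mesoderm genes had a neighbour of any type, against 1 of 10 pluripotency genes, 3 of 13 mesendoderm genes and 1 of 6 definitive endoderm genes. It was present for 2 of 5 neuroectoderm, 3 of 4 extra-embryonic, 3 of 10 cell cycle and checkpoint and 4 of 5 housekeeping genes. These counts have no replicates and were not tested between lists. Neither they nor the span counts were adjusted for the number of start sites per gene. A gene with more start sites has more places where a neighbour can be found. That number ran from 1 (HAND1, MSGN1) to 10 (PDGFRA) in the mesoderm list, and from 3 (HPRT1) to 19 (RPLP0) in the housekeeping list. With basic transcripts alone the count of listed genes with a neighbour was 8. With neighbours limited to protein-coding genes it was 6, made of 2 neuroectoderm genes and 1 each of the pluripotency, mesendoderm, cell cycle and checkpoint and housekeeping genes. Under that limit 0 of 4 extra-embryonic, 0 of 6 definitive endoderm and 0 of 6 mesoderm genes had a neighbour. Neither the basic nor the protein-coding limit was applied to all 19881 protein-coding genes.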

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

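The alternatives below were all chosen after seeing the file, and they concern the annotation alone. Of the 59 listed genes, 17 had another gene's start site within 1000 bp, and 17 had one within 2000 bp. The count was 6 with protein-coding neighbours alone and 8 with basic transcripts alone, both of which leave fewer start sites to count. Start sites spanned more than 1000 bp in 42 genes and more than 2000 bp in 37 genes, and with basic transcripts alone they spanned more than 1000 bp in 19 genes. None of these alternatives was counted over all protein-coding genes of the annotation. No paired analysis was possible because no value of any library was analysed here. For the same reason no normalization, filter, pseudocount, tool, peak threshold or leaving out of replicates was tried for H3K4me1 and H3K27ac.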
